A study of Mus musculus with 12 samples.

How the data were processed

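RNA from BV2 cells was hybridised to 12 Illumina bead arrays. Per the labels' protocols, 400 ng of RNA entered each labelling reaction, and in vitro transcription ran for 12 h. Each of 12 groups held 1 array, taken from the titles in the labels, which do not mention a vehicle. The deposited probe intensities are mean bead signals on a linear scale with no normalization between arrays, as the authors deposited them per the column names, and GenomeStudio 2010.3 is named in the submitters' processing notes. The detection p-value deposited beside each signal ranks the probe among negative control beads, per the file headers and the values, whose smallest step was 1 over 798. The authors' separate value table holds intensities of the same arrays that were normalized by a method not given in the sources used here. By comparison with the signals it is on a linear scale with a floor of 10, at which between 11600 and 11610 values per array lie, and its columns matched their own array best (Spearman 0.953 against at most 0.933 for any other array). Its column medians were 14.884 (non-activated), 14.948 (activated control), 14.914 (E4), 14.946 (E5), 14.965 (E14), 14.959 (E18), 14.927 (E19), 14.910 (E20), 14.957 (E21), 14.965 (E23), 14.962 (E29) and 14.915 (E33). Whether it was centred in another way stays unknown, and it served only as an alternative. There were 0 columns of values without a sample.

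Signals were corrected and normalized with neqc in limma 3.58.1 (R 4.3.3), with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Later steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 were not listed in the annotation used and stay unnamed here, and the gene IDs of 23962 probes were found in the RefSeq gene table, which supplied current symbols. Probe positions were not used here. Each of 16593 genes was represented by its brightest probe over the 12 arrays, a choice that mattered for the 4777 genes with more than 1 probe. Among genes with a second detected probe, the activation differences of both probes correlated with r = 0.913 over 1464 genes, which are not independent, and 210 of 211 genes at least 2-fold different had the same sign on the second probe. Of those 211 genes, 158 were also at least 2-fold different with the same sign on that probe. In total 7362 genes were detected on at least 1 array, 7151 on at least 1 activated array and 5360 on all arrays. The median signal lay between 115.11 (E4) and 125.36 (E14), and the number of arrays limits the precision. Signals near the top of an array's range can understate folds.

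Differences are the activated control minus the non-activated array, and each compound minus the activated control. A gene was measured when its probe had a detection p under 0.01 on at least 1 of the 2 arrays, and was counted as 2-fold different when it was detected on the brighter one. Where the dimmer side was not detected, the fold is a bound, the brighter value over the higher of the dim probe's own value and the lowest detected signal of that array, written "at least N-fold", and no fold is given where that bound is under 1. The counts of 2-fold genes use the normalized difference itself, so they include some genes whose bound is under 2. With 1 array per group these differences have no test. Spread was taken in another way with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), setting the 11 activated arrays against the non-activated one and each compound array against the other 10 activated arrays. There the lone array is assumed to vary like the rest, and differences between compounds count as spread. Where a result is adjusted over the list alone, each list of each comparison was adjusted separately. No correction was made across lists or compounds, so some calls of that kind can arise by chance.

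The text names, for activation, the 14 largest rises and 10 largest falls that were at least 2-fold and had the same sign on all 11 activated arrays, and for each compound up to 6 rises and 6 falls of at least 2-fold with the same sign against the median of the other 9 compound arrays. Unnamed and predicted loci were passed over. It also names up to 4 members of each list with the largest differences, and genes of a panel of 15 inflammatory and stress genes, of which 14 were on the array under their name. The 37 gene lists cover cytokines, chemokines, NF-kB, interferon, antigen presentation, stress responses, lipid and energy metabolism, the cell cycle, microglial identity, housekeeping genes and markers of neurons, astrocytes, oligodendrocytes, fibroblasts and lymphocytes. Some lists share members, and 32 had at least 3 measured members in activation. A list's median was placed among 10000 random lists of the same size matched on mean signal in 20 bins. Unless another reference is named, list medians are of the differences between the 2 arrays of a comparison. Counts of list genes that rose or fell come from limma, which has other reference arrays. The design, the lists, the naming rule and the alternatives tried were fixed, except where the text says otherwise, before the data were examined.

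The steps were tested on simulated data with 200 changed genes among 7151. The noise came from E21 and E23, the most alike pair of compound arrays, and the reference arrays held no changes. In the real fits the reference arrays differ by compound, which adds spread, so the rates below may be too high for them. At a simulated 2-fold change the 2-fold rule called 35% of changed genes and at 3-fold 97.5%, with 0 and 1 unchanged genes called. The limma test of 1 array against 10 called 97% at 2-fold and 99% at 3-fold, with 25 and 27 unchanged genes called. Of 200 lists of 20 unchanged genes, 4.5% lay outside the central 95%, and of 50 lists raised by 0.3 log2 units 100% did. Random lists hold genes drawn singly, whereas members of a real list can vary together, so a percentile can overstate how unusual a list is. Alternatives were median scaling, no normexp background correction, the authors' value table, an offset of 50, detection on both arrays or no detection filter, the mean of all detected probes, a 1.5-fold threshold, the median of the other compound arrays as the reference, limma with a trended robust spread, and leaving out single arrays. For correlations between compounds, unchanged arrays with 1 shared control were simulated 100 times.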

Results

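Transcript levels were measured in BV2 cells, an immortalised mouse microglial line, on 12 Illumina expression bead arrays, with 1 array for each of 12 conditions. In 1 condition the cells were not activated. In another, the activated control, they received 1 µg/ml lipopolysaccharide (LPS, a bacterial cell-wall product sensed by Toll-like receptor 4) and 10 ng/ml interferon-gamma. The other 10 arrays came from cells given the same activation together with 1 of 10 small molecules, which the labels name only as E4, E5, E14, E18, E19, E20, E21, E23, E29 and E33. Cells were collected after 4 h in every condition. The doses and the identities of the compounds are not given in the sources used here, so all compound values below are compared at 1 time and at unstated doses. Each array held signals for 25697 probes, and between 8538 probes (E21) and 9493 probes (non-activated) were detected at a detection p under 0.01. There were no replicates, and the labels do not say whether the 12 samples came from separate cultures, so p-values below measure only the spread between these samples.

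The first question the design poses is what LPS with interferon-gamma did to the BV2 cells within 4 h. Activation raised inflammatory and interferon-response transcripts and lowered transcripts of lipid synthesis. Cxcl9, an interferon-induced chemokine that attracts T cells, rose at least 410-fold and was between 8.85 and 9.57 log2 units above the non-activated array on all 11 activated arrays (limma log2 difference 9.39, SE 0.21, adjusted p 2.02e-12). Cxcl10, its close relative, rose at least 421-fold (limma adjusted p 3.19e-05), and Il1b, which encodes the cytokine interleukin-1 beta, rose 246-fold (limma adjusted p 2.43e-08). In the opposite direction, Gpr183, an oxysterol receptor that guides immune cells, fell at least 24.5-fold (limma adjusted p 2.44e-08). Of 6934 genes measured in this pair of arrays, 685 were at least 2-fold higher and 756 at least 2-fold lower in the activated control, which is 20.8% of them. On the dimmer array 202 of the higher and 225 of the lower genes were not detected, so their folds are bounds. Whether more genes were higher or lower depends on the scaling, with 771 higher and 626 lower when arrays were scaled to a common median.

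Among 12 tested genes of the cytokine list, which also holds the anti-inflammatory genes Il10 and Il1rn (the interleukin-1 receptor antagonist), 7 rose, Il1rn among them, and 0 fell in limma, with 7 also passing when adjusted over the list alone, and the median of the 10 measured members was 4.23 log2 units higher. Il1a rose 197-fold, Tnf (tumour necrosis factor) 31.1-fold, Il6 at least 18.6-fold and Il27 at least 12.8-fold. Of 13 chemokine genes, 8 rose and 1 fell, the same numbers as adjusted over the list alone. The rises included Ccl12 at least 133-fold and Ccl5 58.1-fold, and the monocyte attractant Ccl2 rose 10.6-fold, while Ccl6 fell at least 1.91-fold. NF-kB targets and feedback regulators rose nearly as a block, with 20 of 22 passing over all genes and 22 when adjusted over the list alone. This list had a median of 2.56, and its members included the costimulatory receptor Cd40 at 104-fold, Nfkbiz at 21.2-fold, the ubiquitin-editing enzyme gene Tnfaip3 at 12.5-fold, the adhesion molecule Icam1 at 13.2-fold and the inhibitor gene Nfkbia at 6.78-fold (limma adjusted p 0.0289).

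Interferon targets rose as broadly. For interferon-gamma and IRF1 targets, 20 of 22 genes rose and 0 fell, with 20 also adjusted over the list alone, and the median was 4.36, or 3.82 with undetected members at their bound. Gbp2, a guanylate-binding GTPase of cell-autonomous defence, rose 186-fold (limma adjusted p 6.93e-13). Gbp3 rose 87.2-fold, the immunity-related GTPase gene Ifi47 at least 130-fold, the signalling inhibitor Socs3 49.2-fold and the transcription factor Irf1 33.6-fold. In the type I interferon list, 28 of 29 genes rose (28 adjusted over the list alone), led by the ubiquitin-like Isg15 at 91.0-fold and the antiviral Ifit2 at 67.1-fold, and Ifnb1 itself rose at least 21.9-fold. Antigen presentation by MHC class I rose in 14 of 15 genes (14 adjusted over the list alone), including the peptide transporter Tap1 at least 19.98-fold and the immunoproteasome subunit Psmb9 4.62-fold. For MHC class II and costimulation the result was 1 of 7 in both adjustments, the costimulatory Cd86 at 3.87-fold. Other strong rises were Batf2 at least 117-fold, the vasoconstrictor peptide gene Edn1 at least 99.3-fold, Gbp5 at least 79.5-fold and the early lymphoid activation marker Cd69 at least 58.9-fold.

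The nitric oxide list split, with 5 genes rising and 1 falling of 10 in both adjustments. Nos2, the inducible nitric oxide synthase, rose at least 22.7-fold (limma adjusted p 0.00499), the arginine transporter Slc7a2 17.5-fold and the cofactor enzyme Gch1 6.77-fold, while Arg1, which competes for arginine, fell 1.80-fold. Inflammasome genes rose in 5 of 9 cases (6 adjusted over the list alone), among them Casp4 at 12.5-fold and Il18 at 3.43-fold. Ptgs2, the inducible cyclooxygenase, rose at least 4.21-fold (limma adjusted p 0.00981), while in the eicosanoid list as a whole 1 gene rose and 1 fell of 7, or 2 and 2 adjusted over the list alone. Immediate early genes went both ways, with 6 rising and 3 falling of 16 in both adjustments. Phlda1 rose 15.8-fold and the phosphatase gene Dusp1 5.97-fold, whereas Dusp6 fell at least 10.4-fold, Fos 5.03-fold and Klf2 at least 4.01-fold. In the p53 list 4 rose and 2 fell of 14 in both adjustments, including the death receptor Fas at least 22.01-fold higher, the cell-cycle inhibitor Cdkn1a 5.05-fold higher and Sesn1 10.3-fold lower. Metal response genes rose in 2 of 5 cases in both adjustments, among them the metallothionein gene Mt2 at 2.60-fold.

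Lipid synthesis genes fell. In the list of LXR and fatty acid synthesis genes 5 of 9 fell and 0 rose in both adjustments, with a median of -1.13 (percentile 0 among 10000 random lists matched on signal). The elongase gene Elovl6 fell at least 3.44-fold, the desaturase genes Scd2 and Fads1 2.96-fold and 2.73-fold. Cholesterol synthesis genes had a median of -0.71 (percentile 0.15), and 7 of 17 fell (8 adjusted over the list alone), with the mevalonate pathway gene Mvd 4.43-fold, the sterol carrier gene Stard4 3.60-fold and Dhcr7 at least 2.26-fold lower. The other large falls were those of Lyl1 at least 10.3-fold, Sla at least 8.13-fold, Fam78a at least 11.9-fold, Arl11 15.0-fold, Plxdc1 12.6-fold, Rab7b 12.0-fold, Sash3 10.99-fold and Angpt2 10.6-fold. Hmox1, the haem-degrading enzyme and a target of the antioxidant regulator NRF2, was 4.25-fold lower in the activated control but ranged from -3.19 to 1.09 log2 units over the 11 activated arrays, and did not pass (limma adjusted p 0.522).

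No gene of oxidative phosphorylation (25 tested), tubulins (9) or aryl hydrocarbon receptor targets (3) passed limma in either adjustment. NRF2 targets fell in 2 of 20 cases (1 adjusted over the list alone), heat shock genes rose in 2 and fell in 1 of 12 (2 and 2), ATF4 targets rose in 2 of 27 (2), and unfolded protein response genes rose in 1 and fell in 1 of 16 (0 and 0). Of the S phase genes 1 rose and 1 fell of 22, of the G2 and M phase genes 1 rose and 2 fell of 13, of the hypoxia and glycolysis genes 3 rose of 21, of glucocorticoid receptor targets 2 rose and 3 fell of 9, of alternative activation genes 1 rose and 1 fell of 8, and of microglial identity genes 2 rose and 2 fell of 17, the same numbers in both adjustments. Lysosomal genes fell in 2 of 21 cases (1 adjusted over the list alone), constitutive proteasome genes rose in 1 of 28 (0), and the histone list and the housekeeping list each had 1 fall, of 8 and of 11 (1 each adjusted over the list alone). The median difference of all measured genes was -0.18 log2 units, and -0.05 when arrays were scaled to a common median. Markers of neurons, astrocytes, fibroblasts and lymphocytes were detected on none of the 12 arrays, and of 7 oligodendrocyte markers on the array only Mog and Cnp were detected on any.

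Set against the 11 activated arrays together, limma called 708 genes higher and 1218 lower after activation among 7362 tested. In this test the compound arrays count as activated samples and the lone non-activated array is assumed to vary like them. Leaving out the E29 array raised the total from 1926 to 3079 genes, so that array decides much of the spread.

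The second question is which of the compounds altered the activated state. Against the activated control array, E29 stood apart from the other 9 compounds, with 429 genes at least 2-fold higher and 830 at least 2-fold lower, 19.1% of 6594 measured. E19 followed with 204 genes (70 higher and 134 lower), then E33 with 120, E5 with 96, E20 with 69, E4 with 64 and E14 with 58. The smallest counts were those of E23 (34), E21 (32) and E18 (27). Both the counts and their order depend on the reference, since against the median of the other 9 compound arrays E29 had 1097 genes, E33 105, E19 70, E5 30, E4 24, E20 20, E21 13, E23 6, E18 4 and E14 3. Set against the other 10 activated arrays, limma called 3427 genes for E29 (1864 higher and 1563 lower of 7151 tested) and 9 for E33. For E4, E5, E14, E18, E19, E20, E21 and E23 limma called 0 genes, with 177, 164, 41, 65, 190, 61, 53 and 34 genes at an unadjusted p under 0.05. The E29 array was among the reference arrays of every fit but its own and widened their spread. Few or no calls for another compound therefore do not show that it had no effect. The limma counts of E29 and of the other compounds are not like for like. Folds against the activated control below, those of E29 included, are differences between single arrays. A limma value sets 1 array against the spread of the other 10 activated arrays and does not replicate any compound. All 10 compound comparisons share the 1 activated control array, and 18 genes lay at least 1.5-fold away from that control in the same direction on all 10 compound arrays, among them Evl, Nectin2, Col4a2, Cd80, Serping1, Napepld, Gpr85, Rab43, Cyth4, Pilra, Il10ra and Ccl24 on the lower side and Vegfa and Gadd45g on the higher side. Values for these genes are given with those against the median of the other 9 compound arrays.

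**Figure D1:**
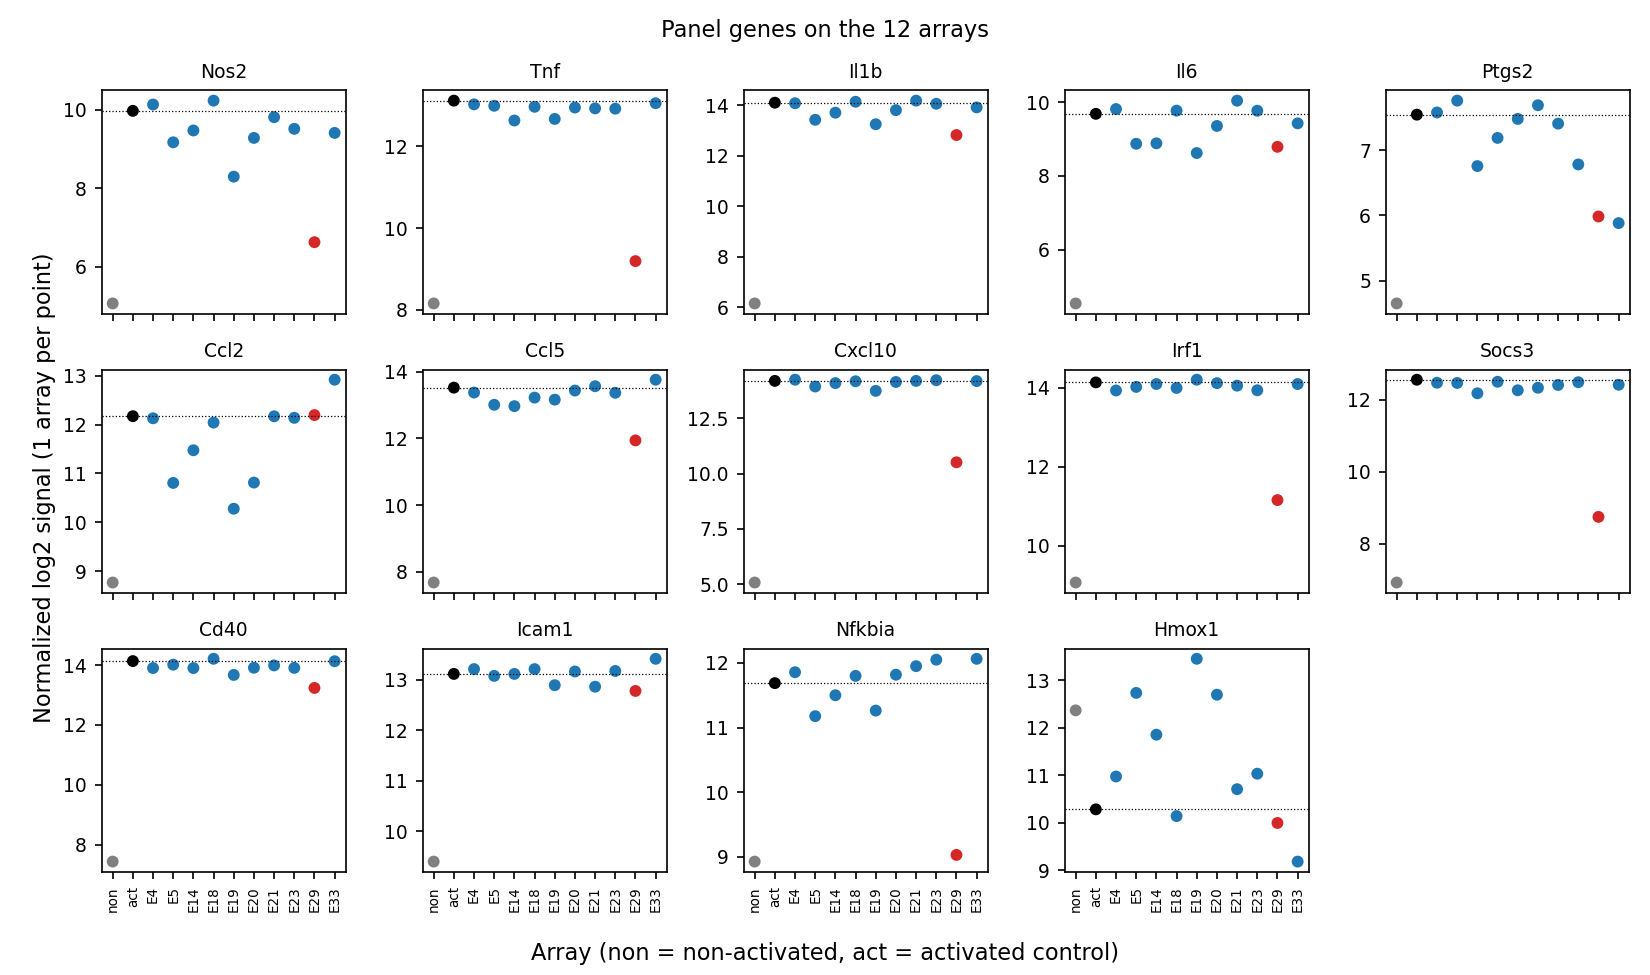
Normalized log2 signal (vertical axes) of 14 inflammatory and stress genes on the 12 arrays (horizontal axis), 1 point per array, with the non-activated array in grey, the activated control in black and dotted, E29 in red and the other compounds in blue. Tnf is 15.2-fold lower under E29 than in the activated control, while Ccl2 differs by 1.01-fold there and Hmox1 is 9.04-fold higher under E19.

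Under E29 a large part of the interferon and NF-kB response fell, while some inflammatory genes did not pass the test and others rose. Tnf fell 15.2-fold against the activated control (limma adjusted p 6.90e-09 against the other activated arrays), the cytokine gene Osm 29.2-fold, Cxcl10 12.8-fold (limma adjusted p 7.64e-09), Nos2 10.2-fold (limma adjusted p 0.000449), Socs3 13.9-fold and Irf1 7.89-fold. The chemokine Cxcl1, a neutrophil attractant, went the other way and rose at least 16.2-fold (limma log2 difference 4.62, SE 0.32, adjusted p 2.11e-07). Ccl2 was 1.01-fold higher (limma adjusted p 0.588), Il6 1.86-fold lower (0.237), Ptgs2 2.95-fold lower (0.0631) and Icam1 1.26-fold lower (0.109), none of them passing the test. The remaining large falls were in the surface receptor Slamf7 (at least 23.03-fold), Batf2 (32.9-fold), Themis2 (at least 21.5-fold), the receptor Hcar2 (22.6-fold) and Rgs1 (19.9-fold). The remaining large rises were in Zswim3 (at least 8.81-fold), Pik3r3 (at least 7.77-fold), Frat2 (at least 6.24-fold), the transcription elongation inhibitor Hexim1 (at least 5.94-fold) and Polg2 (at least 4.64-fold).

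By group, interferon-gamma and IRF1 targets fell under E29 in 16 of 22 cases (18 adjusted over the list alone) with 0 rises and a median of -1.78 log2 units, or -1.40 with undetected members at their bound. Cd274, the ligand of the inhibitory receptor PD-1, fell 11-fold and the transcription factor Irf8 5.86-fold, whereas Gbp2, 1.22-fold lower, passed only when adjusted over the list alone and Cxcl9, 1.12-fold lower, passed in neither adjustment. Both probes were among the brightest of the activated control, at 14.26 and 14.15 log2 units, where a fall can be understated, although Cxcl10 fell from 14.19. Type I interferon genes fell in 21 of 29 cases with 1 rise (21 and 1 adjusted over the list alone), including Mx1 at least 9.14-fold, Cmpk2 5.85-fold and Ifit2 5.54-fold. Of the NF-kB targets 13 fell and 1 rose of 22 in both adjustments, with Nfkbia 6.31-fold, Cd83 4.53-fold and Rel 3.94-fold lower. Of 12 cytokine genes 6 fell and 2 rose in both adjustments, the rises being Il23a (at least 3.88-fold) and Tnfsf9 (1.98-fold). Chemokine genes fell in 4 and rose in 2 of 13 cases in both adjustments. In the MHC class I list 6 fell and 1 rose of 15 in both adjustments, and in the nitric oxide list 3 fell and 1 rose of 10, again in both. Immediate early genes fell in 7 and rose in 4 of 16 cases (8 and 4 adjusted over the list alone), with Atf3 7.07-fold and Klf6 5.14-fold lower but Maff 3.59-fold and Dusp6 at least 3.67-fold higher. Cebpb, which encodes an activator of inflammatory genes, fell 18.3-fold and Atf4 5.29-fold, in an ATF4 list with 10 falls and 3 rises of 27 in both adjustments.

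Genes of S phase, of oxidative phosphorylation and of hypoxia and glycolysis rose under E29 more often than they fell. S phase genes rose in 12 of 21 cases with 1 fall (14 and 2 adjusted over the list alone) and had a median of 0.78 (percentile 100). They included the ribonucleotide reductase subunit Rrm2 (at least 7.36-fold), the cell-cycle transcription factor E2f1 (4.14-fold), Uhrf1 (2.85-fold) and Tk1 (2.65-fold). Oxidative phosphorylation genes rose in 14 of 25 cases with 0 falls in both adjustments, although by small amounts, with a median of 0.38 (percentile 99.2) against 0.10 for all measured genes and 0.20 for housekeeping genes (0.36 and 0.33 for the 2 lists against the other compound arrays) and a largest rise of 1.97-fold in Sdhb. Hypoxia and glycolysis genes rose in 12 of 21 cases and fell in 2 (13 and 2 adjusted over the list alone), with the angiogenic factor Vegfa 5.997-fold (1.44 log2 units against the other compound arrays) and Ndrg1 5.12-fold higher and the hexokinase gene Hk2 2.78-fold lower. The list of histone and transcription-stress genes had 4 rises and 1 fall of 8 in both adjustments and a median of 0.95, with the histone gene H4c9 at 3.31-fold. LXR and fatty acid synthesis genes rose in 6 of 9 cases in both adjustments, Scd2 by 2.98-fold, while cholesterol synthesis genes fell in 6 and rose in 2 of 17. Lysosomal genes rose in 7 of 21 cases (6 adjusted over the list alone) and p53 targets fell in 5 of 14 (5), Mdm2 by 4.40-fold. The efferocytosis receptor Mertk fell 7.86-fold, in a microglial identity list with 5 rises and 2 falls of 16 in both adjustments.

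MHC class II genes rose under E29 in 3 of 7 cases with 0 falls (3 and 1 adjusted over the list alone), eicosanoid genes in 3 of 7, NRF2 targets in 3 of 20 and G2 and M phase genes in 3 of 13 with 1 fall, each the same adjusted over the list alone. Inflammasome genes rose in 1 and fell in 2 of 8 cases and heat shock genes rose in 2 and fell in 1 of 12 in both adjustments. The unfolded protein response list had 3 rises, led by the chaperone gene Dnajb9 at 6.97-fold, and 2 falls, among them Xbp1 at 2.61-fold (2 and 1 adjusted over the list alone). Alternative activation genes rose in 3 and fell in 2 of 8 cases (4 and 2), tubulins rose in 1 and fell in 2 of 9 (1 and 1), constitutive proteasome genes rose in 2 and fell in 4 of 28 (0 and 0), and housekeeping genes rose in 4 and fell in 1 of 11 (4 and 1). There was 1 fall of 5 metal response genes (1), 2 of 9 glucocorticoid receptor targets (2) and 1 of 3 aryl hydrocarbon receptor targets (1). A larger share of all tested genes was called higher under E29 than of NRF2, G2 and M phase, heat shock or constitutive proteasome genes. The same held for unfolded protein response, inflammasome and tubulin genes. Those rises are therefore not particular to these lists, and the median limma log2 difference of NRF2 targets was -0.26. Falls among metal response, inflammasome and tubulin genes and glucocorticoid receptor targets were about as frequent as among all tested genes. The limma result for E29 takes the lone E29 array to vary like the other 10. Of 182 genes with a pair of detected probes and a difference of at least 2-fold, 176 had the same sign on the second probe. Only 118 of them were also at least 2-fold different on that probe.

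On the arrays of E5, E14, E19 and E20 the median of NRF2 targets was higher and that of the cytokine list lower than in the activated control, with 0 limma calls in either list in either adjustment. Hmox1 was 9.04-fold higher under E19, 5.49-fold under E5, 5.34-fold under E20 and 2.98-fold under E14, and 2.48, 1.76, 1.73 and 0.88 log2 units higher against the other compound arrays. The glutathione synthesis gene Gclm was 3.18-fold, 2.62-fold, 2.36-fold and 2.15-fold higher in the same order of compounds, and the sulfiredoxin gene Srxn1 3.40-fold, 2.65-fold, 2.40-fold and 1.97-fold. The medians of the NRF2 list were 0.83 (E19), 0.72 (E5), 0.58 (E20) and 0.36 (E14), each at percentile 100 among random lists, and 0.77, 0.49, 0.49 and 0.32 against the other compound arrays. The median limma differences from the other 10 activated arrays were 0.71, 0.45, 0.42 and 0.09. Of the 18, 17, 15 and 16 members measured, 7, 5, 5 and 3 were at least 2-fold higher. Outside the list, the alcohol dehydrogenase gene Adh7 was at least 3.63-fold (E19), 3.39-fold (E5), 2.69-fold (E20) and 1.20-fold (E14) higher, and the glutathione transferase gene Gsta1 at least 2.03-fold (E19), 2.44-fold (E5) and 1.69-fold (E20). The haem transporter gene Slc48a1 was 3.85-fold (E19) and 2.71-fold (E20) higher. Gsta2 was at least 1.66-fold higher (E20). Osgin1, which is in the NRF2 list, was at least 2.34-fold (E19) and 1.09-fold (E14) higher. None of these genes passed limma over all genes, and those in the NRF2 list did not pass over that list alone. Each of these 4 arrays was set against a reference that held the others of the 4. A difference shared by them therefore widened the spread and was hard to pass.

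The same 4 compounds had lower cytokine medians, -0.64 (E5), -0.60 (E19), -0.51 (E14) and -0.29 (E20), which were -0.36, -0.28, -0.26 and -0.11 against the other compound arrays. Limma called 0 of the 12 cytokine genes under any of them in either adjustment, and its median differences from the other 10 activated arrays were -0.42, -0.29, -0.08 and -0.02. Il27 was 5.37-fold lower under E19, 4.28-fold under E5, 4.00-fold under E14 and 2.91-fold under E20, but differed by -1.33, -1.001, -0.90 and -0.44 log2 units against the other compound arrays. The monocyte attractant Ccl7 was 5.30-fold, 4.24-fold, 1.84-fold and 3.72-fold lower. Ccl2 was 3.72-fold (E19), 2.58-fold (E5), 2.56-fold (E20) and 1.62-fold (E14) lower, and Nos2 3.19-fold, 1.74-fold, 1.61-fold and 1.41-fold, but against the other compound arrays Nos2 differed by -1.18 (E19), -0.30 (E5), -0.19 (E20) and 0.06 (E14). Tnf was at most 1.40-fold lower (E14) in these 4 arrays and differed by between -0.32 (E14) and 0.06 (E5) against the other compound arrays. The chemokine medians were -0.56 (E14), -0.52 (E5) and -0.45 (E19), and -0.23, -0.24 and -0.43 against the other compound arrays, while E20 had -0.10, inside the central 95% of random lists. Nitric oxide list medians lay between -0.44 (E14) and -0.25 (E5), and against the other compound arrays between -0.17 (E19) and -0.02 (E20). Those of NF-kB targets lay between -0.35 (E19) and -0.20 (E20), and between -0.22 (E19) and -0.02 (E20) against the other compound arrays. Limma called 0 genes in these 2 lists under the 4 compounds in either adjustment.

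Further genes differed from the activated control on 1 or more of these 4 arrays. Calls adjusted over a list alone were not corrected across lists or compounds, so some can arise by chance. E19 had Ccl8 6.52-fold, Pilrb1 4.90-fold, the adhesion molecule Vcam1 4.40-fold, the tryptophan-degrading enzyme Ido1 at least 5.09-fold and the complement inhibitor Serping1 at least 6.44-fold lower, and Il6 2.09-fold lower. Against the other compound arrays Pilrb1 differed by -1.16, Vcam1 by -1.29, Ido1 by -1.61 and Serping1 by -1.496 log2 units. Adjusted over the list alone, limma called the chemokine genes Ccl9, Cxcl9 (also in the interferon-gamma list) and Ccl6 lower and the co-chaperone gene Dnaja1 higher under E19, with Ccl9 at 3.58-fold and Cxcl9 at 1.65-fold, while Ccl6 was detected on neither of the arrays compared. Under E20, Ccl8 was 3.16-fold, Pilrb1 3.33-fold and Fos at least 3.22-fold lower and Ptpn14 2.88-fold higher, with Pilrb1 at -0.60 and Fos at -1.08 log2 units against the other compound arrays. Under E14, Ifnb1 was 3.90-fold, Gpr85 3.73-fold, Nectin2 3.18-fold, Serping1 2.98-fold and the costimulatory Cd80 at least 2.86-fold lower, and these differed by -1.21, -0.91, -0.04, -0.11 and -0.67 log2 units against the other compound arrays. Under E5, Eid3 was 3.49-fold and Vegfa 3.16-fold higher, and Gpr85 3.74-fold, Serping1 3.45-fold, Cd69 3.29-fold and Cd80 at least 2.96-fold lower. Of these, Vegfa differed by 0.51, Gpr85 by -0.91, Serping1 by -0.32, Cd69 by -1.06 and Cd80 by -0.45 log2 units against the other compound arrays. Under E20, Cd80 and Col4a2 were at least 2.52-fold and 2.35-fold lower, and -0.46 and -0.68 log2 units against the other compound arrays. Mog, an oligodendrocyte marker, was at least 2.19-fold higher under E5 and at least 1.72-fold higher under E19, and adjusted over its list alone limma called Mog higher and Cnp lower under E5. Also adjusted over the list alone, Itgb2 was higher under E5. ATF4 target medians were 0.41 (E19), 0.22 (E14), 0.21 (E5) and 0.14 (E20), but 0.20, 0.06, 0.01 and -0.11 against the other compound arrays, and the glutathione-degrading enzyme gene Chac1 was 4.81-fold higher under E19 and 2.58-fold under E14, or 1.05 and 0.14 log2 units against the other compound arrays.

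Genes of the amino acid stress response were higher under E4. ATF4 targets had a median of 0.76 log2 units (percentile 100), and 0.67 against the other compound arrays, and 9 of 27 measured members were at least 2-fold higher. Limma called 0 of them over all genes and 9 when adjusted over the list alone, namely Ddit3, Trib3, Asns, Sesn2, Shmt2, Mthfd2, Slc7a1, Mars1 and Slc6a9, and Sesn2 was also called in the p53 list when adjusted over the list alone. Chac1 was 7.74-fold higher (1.73 log2 units against the other compound arrays), Sesn2 5.58-fold, the pseudokinase gene Trib3 3.45-fold, the glycine transporter gene Slc6a9 3.36-fold (1.16 against the other compound arrays), the stress transcription factor Ddit3 2.38-fold and asparagine synthetase, Asns, 2.04-fold. The water and glycerol channel gene Aqp9 was 3.48-fold and Arl11 3.38-fold higher, and Vegfa 3.99-fold higher but only 0.85 log2 units above the other compound arrays. Nectin2, Evl and Serping1 were 3.79-fold, 3.09-fold and 2.84-fold lower and Col4a2 and Rab43 at least 2.52-fold and 2.61-fold lower, but these differences were -0.30, -0.005, -0.04, -0.04 and -0.70 against the other compound arrays. Prm1 was at least 1.62-fold lower, and -0.94 log2 units against the other compound arrays. Of the inflammatory panel, Tnf was 1.06-fold lower, Il1b 1.01-fold lower, Il6 1.09-fold higher and Nos2 1.12-fold higher, and against the other compound arrays all 4 were higher, by 0.10, 0.27, 0.46 and 0.72 log2 units. G2 and M phase genes had a median of -0.34 and cholesterol synthesis genes of -0.26, at percentiles of 0.01, or -0.20 and -0.17 against the other compound arrays, with 0 limma calls in either list in either adjustment.

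Cholesterol synthesis genes were lower under E33. Their median was -0.75 log2 units (percentile 0), and -0.66 against the other compound arrays. The synthase gene Hmgcs1 was 2.23-fold, Hsd17b7 2.08-fold, Cyp51 2.01-fold and Srebf2, which encodes the pathway's main transcription factor, 1.98-fold lower, and limma called Hmgcs1, Idi1, Fdps and Srebf2 lower when adjusted over the list alone (4 of 17) and 0 over all genes. The limma test over all genes called 5 genes higher and 4 lower. Of these, Rbm45, which encodes an RNA-binding protein, was 5.40-fold lower (limma log2 difference -2.34, SE 0.18, adjusted p 9.93e-05), the malonyl-CoA decarboxylase gene Mlycd 2.67-fold higher (limma adjusted p 0.0346), and the p53 target Sesn1 was the only call in any list. The other calls, chosen after their values were seen, were Paip1, Tmem87a and Gtf2a1 on the lower side and Tmem154, Dusp14 and Zfp658 on the higher side. The chemokine gene Cxcl2 was 5.02-fold, the plasminogen activator Plau 4.72-fold, Ido1 4.66-fold, Ifnb1 4.50-fold and Ptgs2 3.16-fold lower, and Ccl24 6.67-fold lower, with Ido1 at -1.19, Ifnb1 at -1.42 and Ccl24 at -1.76 log2 units against the other compound arrays. Fam78a and Arl11, which had fallen on activation, were at least 3.35-fold and 3.74-fold higher, Chac1 3.19-fold, Btbd6 at least 2.13-fold and Gadd45g 3.64-fold higher, with Chac1 at 0.45 and Gadd45g at 1.02 log2 units against the other compound arrays.

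NRF2 targets had a median of -0.32 (percentile 0.02) under E33 and -0.45 against the other compound arrays, with 1 of 14 measured members at least 2-fold lower and 0 of 20 tested passing limma in either adjustment, and Hmox1 was 2.15-fold lower (-1.85 log2 units against the other compound arrays). ATF4 targets had a median of 0.36 and the histone list one of 0.67, both at percentile 100, and 0.26 and 0.35 against the other compound arrays. The calls given next were not corrected across lists or compounds, so some can arise by chance. Adjusted over the list alone, limma also called the oxidase subunit genes Cybb and Ncf4 and the GTPase gene Rac2 higher, with Cybb at 1.49-fold. Abcg1, Tubb5 and H1f2 were called higher and Cxcl2, Ccl24 and Ywhaz lower in the same way, which gives 7 genes higher and 7 lower over the lists. The E33 calls over all genes rose from 9 to 244 when the E29 array was left out of the spread, an alternative chosen after seeing the data. Tnf was 1.04-fold lower, Cxcl10 1.01-fold lower and Ccl2 1.68-fold higher, none passing limma, and they were at 0.13, 0.04 and 0.88 log2 units against the other compound arrays.

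E18, E21 and E23 differed from the activated control in few genes, and Cd207 and Ifi202b were among the higher ones in all 3. Cd207, which encodes the lectin langerin, was 5.68-fold higher under E21, 4.86-fold under E23 and 4.56-fold under E18, and 2.46-fold under E14. The interferon-inducible Ifi202b was 2.89-fold (E21), 2.17-fold (E23) and 2.14-fold (E18) higher. Il10, an anti-inflammatory cytokine gene, was at least 2.90-fold (E21) and 2.33-fold (E23) higher. The alarmin gene Il33 was 2.48-fold, Mustn1 2.46-fold and Sgms2 2.23-fold higher under E21, Ptpn22 2.05-fold higher under E23, and Exog at least 1.32-fold and Zscan20 at least 1.02-fold higher under E18. Tnpo3 and Utrn were detected under E18 but not in the activated control, with no fold above the bound. Fos was 2.68-fold lower under E23 and 2.10-fold under E21, and Ass1 and the complement factor gene Cfb were 2.45-fold and 2.46-fold lower under E23, but against the other compound arrays Fos differed by -0.66 and -0.31, Ass1 by -0.63 and Cfb by -0.24 log2 units. Cyth4, H2-M2, Sirpa and Pilra were 2.81-fold, 2.71-fold, 2.24-fold and 2.21-fold lower under E18, and -0.17, -0.17, -0.49 and -0.05 against the other compound arrays. Under E21, Il10ra was 2.11-fold, Cd80 at least 2.37-fold, Ptpro at least 1.54-fold and Slx4ip at least 1.25-fold lower, and -0.02, -0.02, -0.11 and -0.28 against the other compound arrays. Under E23, Slx4ip was at least 1.41-fold lower and Sprr2e at least 1.19-fold and Slc35e4 at least 1.36-fold higher, and these were at -0.55, 1.26 and 0.23 against the other compound arrays. Evl was 3.69-fold (E23) and 3.19-fold (E18), and Napepld between 2.33-fold and 2.59-fold lower in the 3 arrays, but against the other compound arrays Evl differed by -0.26 and -0.05 and Napepld by between -0.17 and -0.01 log2 units. Tnf was 1.11-fold, 1.14-fold and 1.15-fold lower in E18, E21 and E23, and Il1b was 1.03-fold higher, 1.06-fold higher and 1.03-fold lower. Against the other compound arrays Tnf was at 0.04, -0.02 and -0.03 and Il1b at 0.33, 0.38 and 0.25 log2 units. Limma called 0 genes in any list under these 3 compounds in either adjustment. Of the list medians outside the central 95% of random lists, 6 of 8 under E18, 5 of 10 under E21 and 3 of 8 under E23 had the opposite sign against the other compound arrays.

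**Figure D2:**
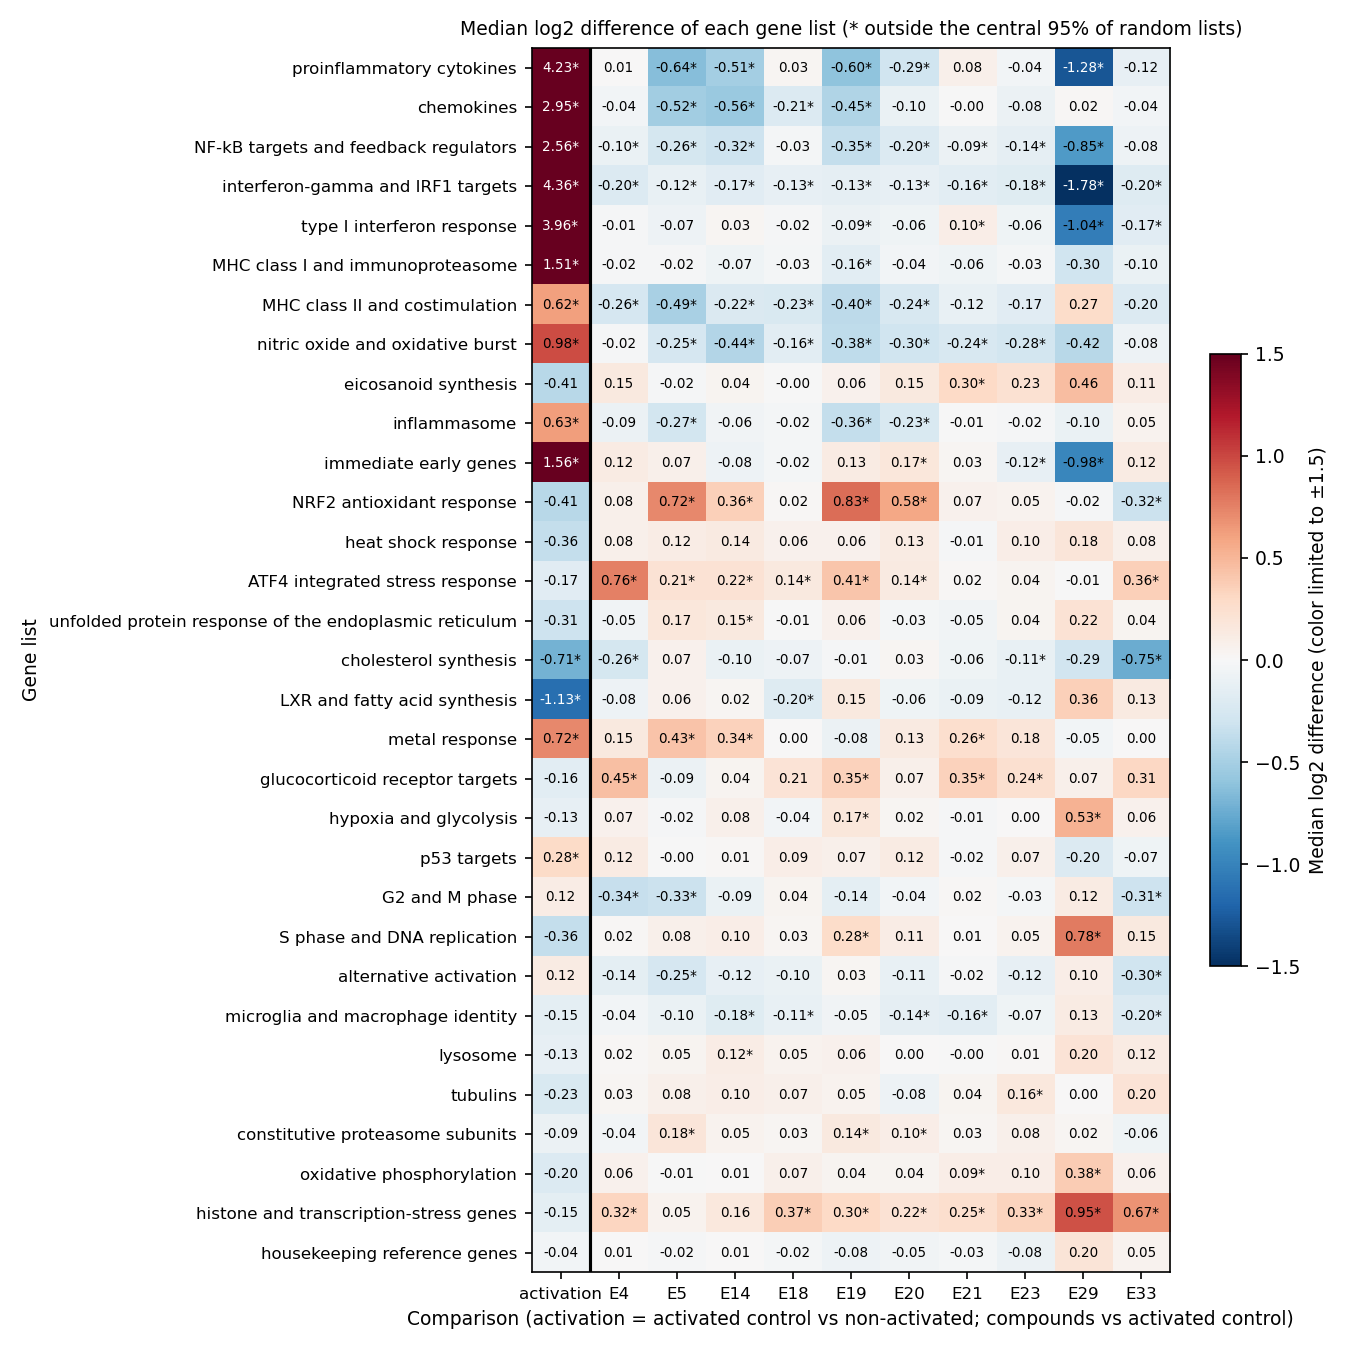
Median log2 difference of 31 gene lists (rows of the grid) after activation and under each compound against the activated control (columns), with color limited to 1.5 log2 units either way and an asterisk where the median lies outside the central 95% of 10000 random lists matched on signal. The NRF2 list is at 0.83 under E19, the ATF4 list at 0.76 under E4 and the cholesterol list at -0.75 under E33.

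How far each compound moved the activation response back was measured over the 685 genes at least 2-fold higher and the 756 at least 2-fold lower in the activated control. Under E29 the raised genes had a median of -1.05 log2 units, and 359 of them (52.4%) were at least 2-fold lower than in the activated control. There 386 were less than 2-fold above the non-activated array, a count that includes any genes below it. E19 came next with a median of -0.31, 105 genes (15.3%) at least 2-fold lower and 193 less than 2-fold above the non-activated array or below it. The other 8 compounds had between 110 (E18) and 171 (E33) such genes, a count that was not repeated with another reference. For the other 8 compounds the medians lay between -0.26 (E33) and -0.12 (E21), with between 12 and 47 genes at least 2-fold lower. The genes lowered by activation had a median of 0.37 under E33 and 0.25 under E29, with 35 and 123 of them at least 2-fold higher. Because the activated control enters both differences, its chance error alone pulls these medians toward reversal. With the median of the other 9 compound arrays in its place, the raised genes had a median of -0.92 under E29 (281 of 592 genes at least 2-fold lower), -0.12 under E19 (35 of 586), -0.08 under E33 and between -0.03 and 0.10 under the other 7. The lowered genes then had a median of 0.29 under E33 (26 of 645 genes at least 2-fold higher) and 0.15 under E29 (76 of 635).

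The compounds were also compared with one another, over 7151 genes, which are not independent replicates. E21 and E23 were the most alike pair, with a Pearson correlation of 0.773 between their differences from the activated control, 1 gene at least 2-fold different between the arrays, and a standard deviation of 0.18 log2 units between them. E5 and E19 had a correlation of 0.768, E19 and E20 0.766, E14 and E19 0.693 and E5 and E20 0.688. E18 had correlations of 0.673 with E23 and 0.667 with E21. Sharing 1 control array gives a correlation by itself, and unchanged arrays simulated against a shared control had 0.499 and a covariance of 0.017, with the noise taken from E21 and E23, so it may be understated. The covariance exceeded that value by 0.041 for E21 and E23, 0.087 for E5 and E19, 0.075 for E19 and E20 and 0.0996 for E19 and E29, whose correlation was 0.348. E5 and E19 shared 28 higher and 50 lower genes, where independent lists of those sizes would share 0.352 and 1.12, and E19 and E20 shared 18 and 42 against 0.186 and 0.937. The control array cannot be split, and part of these excesses may come from it. With the median of the other 8 compound arrays as the reference the correlations were 0.607 (E21 and E23), 0.580 (E5 and E19), 0.546 (E19 and E20), 0.458 (E18 and E21), 0.450 (E5 and E20), 0.327 (E14 and E19) and 0.175 (E19 and E29). With 1 array per compound, no interval can be given for the difference between any pair of compounds at a single gene.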

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

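The alternatives without the E29 array, for compounds, were chosen after seeing the data. All other alternatives were planned. Of 106 alternative values for the 12 counts of 2-fold genes, 55 stayed within 1.5 times and 51 moved. The 160 alternative values for the medians over activation genes moved by less than the robust standard deviation of single genes, a wide limit for a median. Against the other compound arrays the median of raised genes turned from negative to 0.05 (E4), 0.06 (E18), 0.008 (E20), 0.10 (E21) and 0.02 (E23), and that of lowered genes from positive to -0.02 (E4), -0.05 (E20), -0.05 (E21) and -0.02 (E23). Of 938 alternative list medians 877 stayed within the same limit, 36 moved and 25 reversed. Of 75 alternative limma counts 69 stayed and 6 moved, but most of those that stayed were 0 calls in both settings. Of 1711 alternative values for named genes 1312 stayed and 399 moved. The sign was judged only for named genes at least 2-fold different, of which 0 reversed, and some smaller differences turned against the other compound arrays, among them Nos2 under E14 (0.06) and E23 (0.10), Ptgs2 under E19 (0.29) and Tnf under E5 (0.06). Of 105 compound list medians outside the central 95%, 82 kept their sign against the other compound arrays. No paired analysis was possible because each group holds 1 array. The fit with the chip as a term was not run, because the file headers give no chip. Signal over background limits what can be seen, since between 33.2% (E21) and 36.9% (non-activated) of probes were detected and folds of undetected genes are bounds.

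Without normexp correction, which leaves background in both arrays and so compresses folds, 417 genes were at least 2-fold higher and 274 lower after activation, and the compound counts were 18 (E4), 28 (E5), 17 (E14), 3 (E18), 71 (E19), 29 (E20), 4 (E21), 5 (E23), 501 (E29) and 20 (E33). An offset of 50, which compresses folds in the same way, gave 453 lower genes after activation and 32 (E4), 54 (E5), 34 (E14), 12 (E18), 108 (E19), 12 (E21), 18 (E23), 788 (E29) and 43 (E33). The authors' table gave 111 (E4), 156 (E5), 101 (E14), 81 (E18), 119 (E20), 59 (E21), 67 (E23) and 213 (E33), and the cause was not tested. At 1.5-fold, a lower threshold, activation had 1105 higher and 1749 lower genes, and the compounds 389 (E4), 559 (E5), 321 (E14), 300 (E18), 705 (E19), 333 (E20), 262 (E21), 267 (E23), 2801 (E29) and 819 (E33). Against the median of the other 9 compound arrays the counts were 24 (E4), 30 (E5), 3 (E14), 4 (E18), 70 (E19), 20 (E20), 13 (E21), 6 (E23), and within 1.5 times 1097 (E29) and 105 (E33). Detection on both arrays, which measures fewer genes, gave 483 higher and 531 lower genes after activation and 863 genes for E29. It gave 21 for E21 and an MHC class II median of 0.017 for E5 in place of -0.49. Using no detection filter adds list members detected on neither array, giving 24 in place of 15 immediate early genes and 15 in place of 7 LXR genes. The immediate early median after activation was then -0.022 in place of 1.56 and the LXR median under E18 0.006 in place of -0.20. For the compounds limma then tested 16593 genes in place of 7151, and its counts for E4, E21 and E33 rose.

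Against the other 9 compound arrays these list medians reversed. NF-kB targets were at 0.096 (E4), 0.15 (E21) and 0.055 (E23) in place of -0.10, -0.09 and -0.14. Interferon-gamma targets were at 0.012 (E4), 0.016 (E5), 0.06 (E18), 0.016 (E20), 0.039 (E21), 0.025 (E23) and 0.015 (E33), where all 7 had lain between -0.20 and -0.12. Metal response genes were at -0.021 (E14). Under E18, chemokines were at 0.032, MHC class II at 0.02, nitric oxide genes at 0.10, ATF4 targets at -0.027 and identity genes at 0.011. Under E20, ATF4 targets and the histone list were at -0.11. Under E21, nitric oxide genes were at 0.023, identity genes at 0.025 and the histone list at -0.06, and under E23 nitric oxide genes at 0.085. The cause was not tested.

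Leaving out each activated array in turn gave between 1722 and 3079 limma calls for activation, against 1926, and the E29 array decides the upper end, since without it the count was 3079. Without the E29 array limma called 1 gene for E4 and 244 for E33. The share of higher genes moved by over 10 points as follows. Without normexp it was 60.4% for activation (47.5% in the main setting), 77.8% for E4 (56.3%), 25% for E5 (37.5%), 50% for E21 (34.4%) and 20% for E33 (45.8%). In the authors' table it was 39.6% for E14 (17.2%), 48.2% for E18 (25.9%), 45.8% for E21, 32.8% for E23 (17.6%) and 60.6% for E33. With an offset of 50 it was 71.9% for E4 and 27.9% for E33. Against the other compound arrays it was 91.7% for E4, 66.7% for E5 and E14, 75% for E18, 70.0% for E20 (27.5%), 92.3% for E21 and 83.3% for E23. With detection on both arrays it was 26.1% for E5 and 13.6% for E18. At 1.5-fold it was 50.3% for E5, 36.5% for E14, 45.3% for E18, 48.9% for E19 (34.3%), 40.2% for E20, 33.3% for E23 and 49.7% for E29 (34.1%).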

Other observations

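The tests of a dim E29 array, of weaker activation of the E29 culture and of the NRF2 relation were chosen after the result was seen, and the other 3 were written before.

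Short-lived transcripts outside the lists of the report also fell under E29. Of 31 genes on a list of such transcripts, 20 were measured, and 12 fell and 4 rose in limma (adjusted p under 0.05) against the other activated arrays. Rhob, a small GTPase gene, was at -3.30 log2 units against the activated control (limma adjusted p 2.36e-08), the transcriptional repressor Bcl6 at -3.77 (6.20e-07), the anti-proliferative Btg1 at -2.15 (1.02e-05) and the survival gene Mcl1 at -1.58 (9.45e-06). The kinase gene Plk3 was at 2.45 (limma adjusted p 0.000264) and the mRNA decay factor Zfp36l1 at 2.60 (1.14e-05), although both had been lower after activation, at -1.16 and -2.83.

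Among the activated arrays, 1 pattern was that 18 genes differed from the activated control by at least 1.5-fold in the same direction on all 10 compound arrays, 2 of them higher and 16 lower. With each of the 9 compound arrays other than E29 as the reference in its place, between 0 and 68 genes did so, but the upper end is E33 alone, and without it the range was 0 to 15. The count of 18 lies inside the range only with E33, so a deviation of the activated control array or culture stays open. An effect common to all 10 compounds, or of a solvent, stays open too and was not tested, since the labels name no vehicle.

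Another pattern was that genes raised by activation had a median difference from the control below 0 on all 10 compound arrays, although single genes went the other way. For 587 activation genes picked without the control, the control was still 0.133 log2 units above the median of the compound arrays (quartiles -0.04 and 0.32, 95% bootstrap interval over genes 0.105 to 0.159), with 412 genes above 0. This argues against chance error of single genes on the control array as the whole cause. A shift shared by many genes in that 1 array or culture stays open, and genes are not independent, so the interval may be too narrow.

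The last pattern was the 1259 genes at least 2-fold different under E29. A dim array is argued against, because E4, the next dimmest (median shift -0.18 against -0.21 log2 units), had 64. Weaker activation of the E29 culture alone is argued against too, because 482 of the 1259 genes (38.3%) were activation genes moving back and 714 were not activation genes. Loss of short-lived transcripts stays open. The median of the short-lived list was -1.02, at percentile 0 among random lists, although some members rose. Those random lists were matched on signal and not on the activation difference. Genes raised by activation had a median of -1.05 under E29. Of the falling members named above, Rhob had been at 2.24, Btg1 at 2.09, Mcl1 at 0.68 and Bcl6 at 0.06 after activation. The percentile therefore cannot tell short life from reversal of activation. A hypothesis is that E29 may act on transcription or RNA stability, which these arrays cannot test and which nascent RNA and RNA decay measured in repeat cultures would, and without a second array of E29 a difference of that culture cannot be excluded.

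A separate hypothesis was that compounds that raise NRF2 targets lower cytokine transcripts. Across the 10 compounds, the NRF2 and cytokine list medians had a Pearson r of -0.316 (permutation p 0.382, adjusted 0.653) and a Spearman rho of -0.309 (permutation p 0.389, adjusted 0.486), adjusted over 5 relations with 100000 permutations. Without E19 and E5, the compounds farthest from the median NRF2 value, r was -0.084, and without E29 it was -0.821, so single compounds decide it, and against the other compound arrays it was -0.348. For chemokines r was -0.719 (permutation p 0.0177, adjusted 0.0883) and rho -0.624 (permutation p 0.0601, adjusted 0.150), and r was -0.446 without E19 and E5 and -0.824 against the other compound arrays. The other 3 relations had an r of -0.152 for NF-kB targets (-0.844 without E29), 0.284 for interferon-gamma targets (rho 0.624, 0.721 for r without E29) and 0.241 for type I interferon genes, which were -0.388, 0.112 and 0.199 against the other compound arrays, with adjusted permutation p of 0.700, 0.653 and 0.653 for r. No relation passed the adjustment, and the hypothesis remains untested beyond these 10 arrays, which also share 1 control.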
